A study of Homo sapiens with 6 samples.

How the data were processed

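Total RNA of SK-Hep1 cells was labelled with biotin as cRNA and hybridised to Illumina HumanHT-12 bead arrays, per the labels. The 6 arrays comprise 3 siLuc controls and 3 siTARDBP knockdowns, and each was assigned to its group by its title. No label says that the 3 samples of a group were separate cultures.

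The deposited non-normalised table holds 1 intensity per probe and array on a linear scale, which the submitters' processing notes credit to BeadStudio (version not given in the sources used here). It holds no detection p-values and no control probes, and whether the authors subtracted background is not given in the sources used here. The smallest values (26.2 to 31.6 signal units per array) and the floor of the distribution lie well above 0, as in a table without background subtraction. A second deposited table holds log2 values that the authors normalised to 1 common distribution, with a median of 6.12 in each of the 6 columns. Each of its columns correlated with log2 of the same array's intensity with r between 0.9987 and 0.9997, so its scale is log2, it is not centred per gene, and higher values mean brighter probes. The target of that normalisation differs from the mean distribution of these 6 arrays, and its tool is not given in the sources used here. This second table was used only as an alternative.

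The analysis was fixed before the data were examined, with a fallback for a table without detection p-values. The preferred background correction, limma's neqc with an offset of 16, needs detection p-values or control probes and could not be used, so the fallback became the main setting. Intensities were background corrected with normexp (saddle-point approximation, offset 50), quantile normalised and log2 transformed in limma 3.58.1 under R 4.3.3. A probe was kept when its value exceeded the array's median on all 3 arrays of at least 1 group, which left 20438 of 47231 probes. Normexp with an offset compresses the changes of dim probes, and a filter at the array median admits probes near background.

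Probes were named from the platform annotation, with symbols updated through the gene identifier (30074 probes) or the accession (18 probes) against the RefSeq gene table of assembly GRCh38.p14, and 29 kept the name as given. In all 30113 probes had 1 gene symbol, 8 had several and 17110 were not listed with a gene. No coordinates are given because the sources used here name no genome build for the probes. Probes without a single symbol were left out of gene counts (5126 of the kept probes). Each gene was represented by its brightest probe, which gave 11391 genes. Of the 111 named genes, 45 had other tested probes. In 23 of these another probe passed the threshold in the same direction, and in 8 another probe had the opposite sign (CD34, CD68, ELOVL6, PMAIP1, SF1, TARBP2, TGFBR2 and YWHAZ), past the threshold in CD68 alone.

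Groups were compared with limma (lmFit, eBayes without trend or robust fitting, no covariates), siTARDBP minus siLuc, and p-values were adjusted by Benjamini-Hochberg over the 11391 genes, with a threshold of 0.05. Adjusted p-values in the text are of this kind unless a list is named. SE is limma's moderated standard error of the log2 change, and the median SE over all genes was 0.098. The named genes are TARDBP and PFKP, the 12 largest rises and 12 largest falls among genes past the threshold with non-overlapping groups (leaving out LOC, HS. and FLJ symbols and open reading frames named by chromosome), and of each list up to 4 members past the threshold with the largest change, or up to 2 with the smallest p if none passed. A few further list members (PGK1, PDK1, HK1, LDHA, GAPDH, PKM, CKS2, CEP72, AGRN, PRPS2, VIM and ALB) and genes with opposed probes were named after their values were seen.

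The 33 gene lists were assembled from general knowledge and not from these arrays. They were tested with limma's camera (preset correlation 0.01) against all other tested genes, with Benjamini-Hochberg adjustment over the 32 lists that had at least 5 tested genes. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, were run beside it. Counts adjusted over the list alone use Benjamini-Hochberg within the list. Glycolysis and PFKP were singled out beforehand because work on the TARDBP protein in liver cancer cells is known for them. Whether that work used these arrays was not checked, so the results for glycolysis and PFKP are not an independent test.

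Without control probes, a background limit was estimated after the data were seen. It was the mode of each array's log2 signal plus 1.645 SDs of its lower side. This limit would exceed 95% of noise that is normally distributed on the log2 scale. It lay between 80.1 and 125 signal units. Of the tested genes, 1168 exceeded it on no array, 12 of them among the 1313 changed. Where a gene exceeded it on no array of a group, its change is given as at least N-fold, from the brighter group's mean to the mean of, per array, the limit or the probe's own value, whichever was higher.

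The gene test was tested on simulated data with the spread of these arrays, in which 200 of 11391 genes were changed. It recovered 38.2% of the genes changed 1.3-fold, 76.6% at 1.5-fold, 98.2% at 2-fold and 99.8% at 3-fold, and 3.8% of its calls were false. The simulated changes were added after background correction, so they escaped the compression that the offset puts on real changes of dim probes. The 200 changed genes were also fewer than the 1313 called in the data. These shares are therefore not the power for real fold changes, least of all in dim genes. In simulated lists of 25 genes shifted by -0.15, camera found 10 of 10 with either correlation at an unadjusted p under 0.05. At that threshold it also called 1 of 10 unshifted lists with the preset and 0 with the estimated correlation. Every simulated member moved by the same amount with independent noise, and the real lists were judged by adjusted p. The recovery therefore does not give the power for the real lists.

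Alternatives covered the background correction, the scaling between arrays, the authors' log2 values, the filter, the probe rule, the variance prior, array weights, the replicate numbers as a block, and each array left out in turn. An ordinary linear model, a minimum fold and other list tests were tried as well.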

Results

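Gene expression was measured on 6 Illumina bead arrays of SK-Hep1, a human line labelled as hepatocellular carcinoma. In 3 samples the cells carried a knockdown of TARDBP (siTARDBP), and 3 control samples were labelled siLuc, the usual name of an siRNA against luciferase, a gene that human cells lack. TARDBP encodes TDP-43, an RNA-binding protein that regulates splicing and represses non-conserved, so-called cryptic exons. The series was designed to ask what role TARDBP has in hepatocellular carcinoma cells. Each array carried 47231 probes, and its mean raw signal lay between 375 and 464. The estimated background of the siLuc 2 and siTARDBP 2 arrays was 58.9 and 59.3 signal units, lower than that of the other 4 arrays (71.5 to 75.9). Between 29.1% and 35.1% of the probes of an array exceeded the estimated background limit. Across probes, which are not independent replicates, arrays of 1 group correlated with r between 0.992 and 0.993, and arrays of different groups with r between 0.989 and 0.992. The number of arrays, 3 per group, limits the precision of each comparison, and the p-values measure only the spread between these arrays, which may be technical.

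TARDBP itself was lower in every siTARDBP array than in every siLuc array. Its probe read 7.86 ± 0.149 (normalised log2 intensity, SD, n = 3) with siLuc and 6.88 ± 0.156 (n = 3) with siTARDBP, so it fell by 0.98 (SE 0.105), a 1.98-fold decrease (limma, Benjamini-Hochberg adjusted p = 2.62e-06). The 3 siLuc arrays gave 7.95, 7.95 and 7.69, and the 3 siTARDBP arrays 7.05, 6.82 and 6.75. The raw signal of this probe dropped from 228 ± 32.9 to 106 ± 27.1 (n = 3 each), and 2 of the 3 siTARDBP arrays still exceeded the background limit. After removal of each array's background mode the decrease was 4.25-fold (2 to 8.24 over pairs of arrays), so the size of the knockdown is uncertain. The fall did not pass in an ordinary linear model without moderated variances (adjusted p = 0.0643), nor when tested against a minimum of 1.5-fold (limma's treat, adjusted p = 0.195). TARDBPP3, a processed pseudogene of TARDBP, gave the largest fall of the 11391 genes tested: its brighter probe moved from 9.35 to 7.12, a change of -2.23 (SE 0.0922, adjusted p = 3.36e-12). Its dimmer probe was above the background limit on 1 siLuc array and on no siTARDBP array. A pseudogene probe can bind the transcript of the parent gene, so the TARDBPP3 value is uncertain as a measure of the pseudogene.

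**Figure D1:**
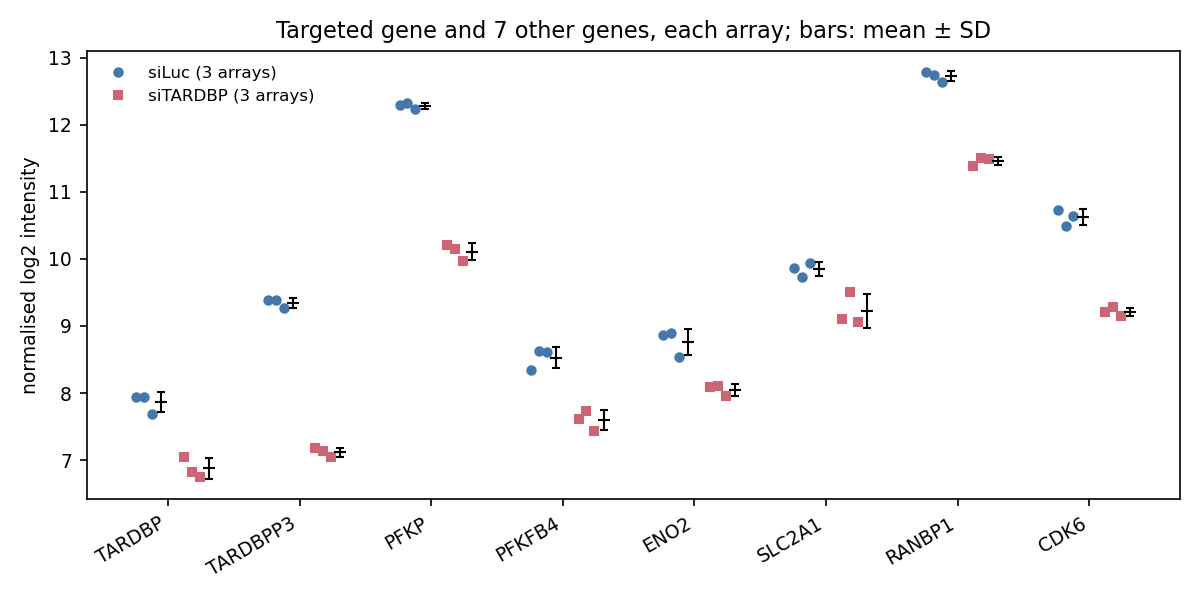
Normalised log2 intensity (vertical axis) of TARDBP and 7 other genes on each of the 3 siLuc arrays (circles) and 3 siTARDBP arrays (squares), with bars for mean ± SD. For all 8 genes the siTARDBP values lie below the siLuc values, from a difference of -0.63 for SLC2A1 to -2.23 for TARDBPP3.

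The knockdown arrays differed from the controls in 1313 of 11391 genes (11.5%), of which 590 rose and 723 fell (limma, adjusted p under 0.05). Most changes were small, with a median absolute log2 change of 0.40 among changed genes, and 10 genes rose and 15 fell at least 2-fold. Apart from TARDBPP3, the largest fall belonged to PFKP, the platelet-type phosphofructokinase that catalyses the committed step of glycolysis. PFKP intensity was 12.28 ± 0.043 with siLuc and 10.11 ± 0.12 with siTARDBP (n = 3 each), a change of -2.17 (SE 0.0943) or 4.5-fold lower (adjusted p = 4.33e-12), and its raw signal dropped from 5229 ± 453 to 1048 ± 253. A second PFKP probe stayed below the background limit on all 6 arrays and was not tested.

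Large falls also included NPPB, the natriuretic peptide B precursor (-1.49, SE 0.126), CDK6, a cyclin-dependent kinase of the G1 phase (-1.41, SE 0.0951), AK4, a mitochondrial adenylate kinase (-1.39, SE 0.121), and USP13, a deubiquitinase (-1.37, SE 0.0933). RANBP1, a regulator of the nuclear transport GTPase Ran, fell by 1.26 (SE 0.0919), and its second probe changed by -1.16. ANKRD46 (-1.19), HIBADH (-1.18), an enzyme of valine breakdown, APLP2 (-1.13), a homologue of the amyloid precursor protein, and PTBP3 (-1.07), a splicing regulator, completed the named falls together with SNAR-A1 (-1.47). The last is 1 copy of a family of near-identical small RNAs, so its value is uncertain. Adjusted p-values of these 10 genes lay between 8.52e-09 and 3.29e-06 (limma).

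Among the genes that rose, CDC42SE2, a small effector of the GTPase CDC42, changed most, from 7.70 ± 0.134 to 9.28 ± 0.135 (n = 3 each), a log2 change of 1.58 (SE 0.101, limma adjusted p = 4.37e-09). MED28, a Mediator subunit, rose by 1.39 (SE 0.0961), CCDC32 by 1.37 (SE 0.0966), PPDPF by 1.29 (SE 0.0912) and NACC1, a transcriptional repressor, by 1.17 (SE 0.0933). WDFY1 (1.14), the endosomal sorting subunit VPS25 (1.12), the arginine sensor CASTOR1 (1.04), the transcription factor STAT3 (0.99), the focal adhesion protein paxillin (PXN, 0.99) and the kinase SIK1 (0.98) followed. All 3 tested STAT3 probes rose, the other 2 by 0.97 and 0.98. PKD1L1-AS1, an antisense RNA, rose by 1.07.

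**Figure D2:**
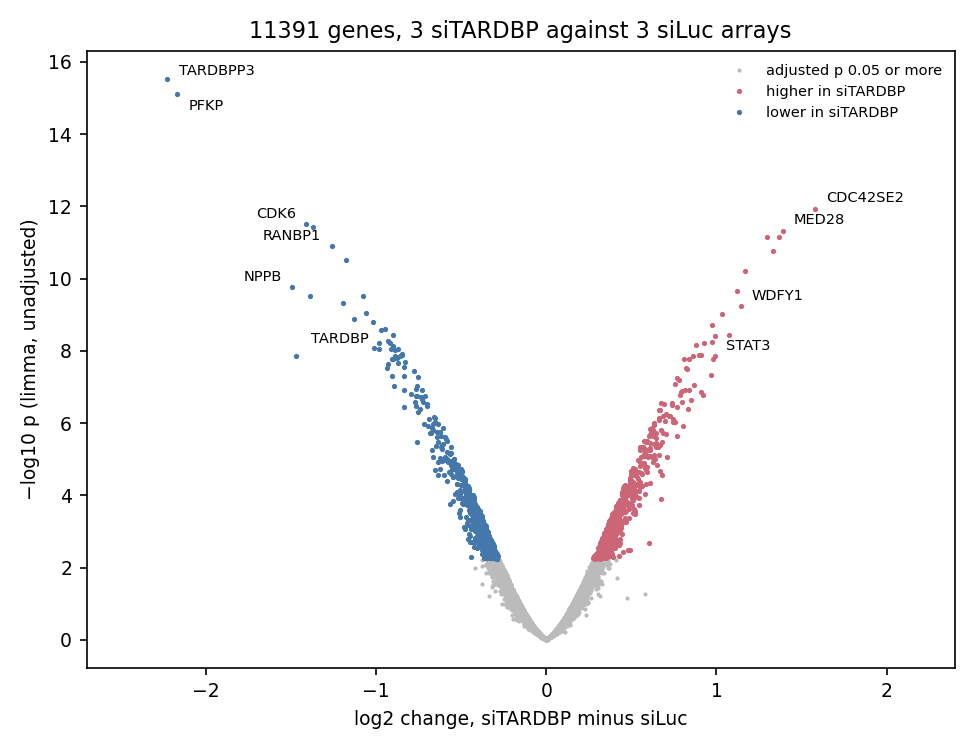
Log2 change, siTARDBP minus siLuc (horizontal axis), against -log10 of the unadjusted limma p (vertical axis) for 11391 genes, 1 point per gene, with coloured points for adjusted p under 0.05. PFKP (-2.17) and TARDBPP3 (-2.23) stand apart at the upper left, and CDC42SE2 (1.58) is the farthest point on the right.

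The balance of rises and falls depended on the scaling between arrays. Scaling each array to its median left 735 changed genes, 159 higher and 576 lower (78.4% lower, against 55.1% with quantile normalisation). Without the arrays siLuc 2 and siTARDBP 2, whose background was lower, 573 genes passed, 293 higher and 280 lower.

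Of 24 tested glycolysis genes, 7 fell and none rose (7 and 0 adjusted over the list alone), 18 had negative changes, and the median log2 change was -0.14. The list passed limma's camera test with a preset correlation of 0.01 (adjusted p = 0.00354 over 32 lists) and did not pass with a correlation estimated from the arrays (adjusted p = 0.369 with an estimated correlation). The falls were those of PFKP (-2.17), PFKFB4 (-0.93, SE 0.105), which sets the level of an activator of phosphofructokinase, the enolase ENO2 (-0.72, SE 0.104), the glucose transporter SLC2A1 (-0.63, SE 0.113), PGK1 (-0.45), hexokinase HK1 (-0.44) and PDK1, a kinase that inhibits pyruvate dehydrogenase. PDK1 was not above the background limit on any siTARDBP array, so the size of its fall is not given. LDHA (-0.13, adjusted p = 0.436), GAPDH (-0.05, adjusted p = 0.791) and PKM (0.22, adjusted p = 0.273) did not pass. Another 4 lists passed with the preset correlation, and none of the 32 lists passed with an estimated correlation.

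Of 55 G2/M cell cycle genes, 11 fell and 1 rose (15 and 2 adjusted over the list alone), with a median change of -0.15 (camera adjusted p = 0.00354, and adjusted p = 0.421 with an estimated correlation). CENPE, a kinetochore motor, fell by 0.85 (SE 0.0922), CDCA3 by 0.76 (SE 0.0979), HMMR by 0.57 (SE 0.104) and CDC20, an activator of the anaphase-promoting complex, by 0.43 (SE 0.0916). CKS2 was the member that rose (0.33). Of 43 G1/S genes, 10 fell and none rose (11 and 0 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.00504, and adjusted p = 0.369 with an estimated correlation). The replication licensing factor CDT1 fell by 0.53 (SE 0.0931), the helicase HELLS by 0.46 (SE 0.094), the phosphatase CDC25A by 0.43 (SE 0.101) and the flap endonuclease FEN1 by 0.42 (SE 0.0974). The second probes of HELLS (-0.18), CDC25A (-0.08) and FEN1 (-0.10, at 9.1 with siLuc) had the same sign but did not pass. CDC25A no longer passed without the siLuc 1 array (adjusted p = 0.0536) or as the mean over its probes (adjusted p = 0.0724). With median scaling, which moved the median of all genes from -0.02 to -0.09, the medians of the G2/M and G1/S lists were -0.27 and -0.26.

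Genes in which loss of TDP-43 is known to admit cryptic exons formed another list that passed. Of 12 tested members 5 fell and 1 rose (5 and 3 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.0141, and adjusted p = 0.421 with an estimated correlation). PFKP and RANBP1 belong to it, as do RNFT2 (adjusted p = 2.33e-05), the autophagy protease ATG4B (-0.61, SE 0.0991) and CEP72 (-0.39), and AGRN was the member that rose (0.40). RNFT2 was not above the background limit on any siTARDBP array, so its decrease was at least 1.32-fold. Without PFKP the list did not pass (adjusted p = 0.245), nor did it without the siTARDBP 2 array (adjusted p = 0.0622). Its median was -0.08 without the siLuc 1 array and -0.25 without the siLuc 3 array.

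Of 14 tested fatty acid synthesis genes, 3 fell and none rose (7 and 0 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.0141, and adjusted p = 0.384 with an estimated correlation). GPAM, the acyltransferase that starts glycerolipid synthesis, fell by 0.44 (SE 0.0956), the desaturase SCD by 0.37 (SE 0.0944) and the elongase ELOVL6 by 0.29 (SE 0.0905). The second ELOVL6 probe had the opposite sign. Without the siTARDBP 2 array the list did not pass (adjusted p = 0.0519).

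**Figure D3:**
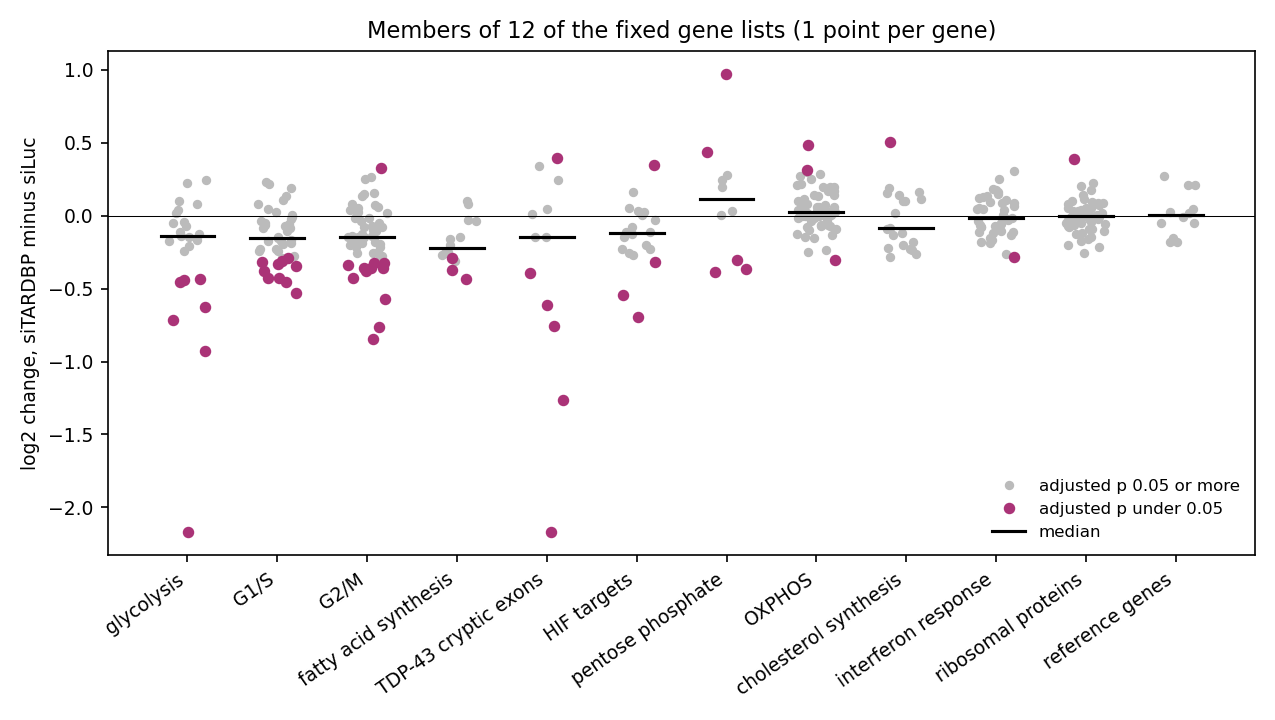
Log2 change, siTARDBP minus siLuc (vertical axis), of each tested member of 12 gene lists, 1 point per gene, with a line at the list's median and dark points for limma adjusted p under 0.05. The medians of glycolysis (-0.14), G1/S (-0.15), G2/M (-0.15) and fatty acid synthesis (-0.22) lie below 0, and that of the reference genes at 0.00.

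Other metabolic lists did not pass. Among 20 targets of hypoxia-inducible factor outside glycolysis, 3 fell and 1 rose (3 and 1 adjusted over the list alone), with a median of -0.12 (camera adjusted p = 0.124). BNIP3, a mitophagy receptor, fell by 0.69 (SE 0.101), the collagen hydroxylase P4HA1 by 0.54 (SE 0.0952) and ANKRD37 by 0.32, while LOX rose by 0.34. This list passed with median scaling (adjusted p = 0.0463), without the siLuc 3 array (adjusted p = 0.0388) and with no filter on dim probes (adjusted p = 0.0471). In the pentose phosphate list, 2 of 10 genes rose and 3 fell (4 and 3 adjusted over the list alone, adjusted p = 0.343). RPIA, the ribose-phosphate isomerase, rose by 0.97 (SE 0.0943) and PRPS1 by 0.43, and DERA (-0.39), RPE (-0.37) and PRPS2 (-0.30) fell. Of 69 oxidative phosphorylation genes, 2 rose (UQCR10 by 0.49 and ATP5F1D by 0.32) and NDUFB10 fell by 0.30, with 1 rise and no fall adjusted over the list alone (adjusted p = 0.185, and 0.0365 without the siTARDBP 1 array, where the median was 0.04). Among 20 cholesterol synthesis genes, INSIG1, a brake on sterol synthesis, rose by 0.51 (SE 0.0904) and none fell, likewise adjusted over the list alone (adjusted p = 0.875).

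The lists of RNA-binding proteins and microRNA processing did not pass the camera test. For comparison, 11.5% of all tested genes changed. Of 34 hnRNP and FET family genes, 4 rose and none fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.296), namely TIAL1 (0.59, SE 0.105), HNRNPL (0.45, SE 0.0985), CELF1 (0.35) and PTBP1 (0.31). With median scaling, which moved the median of all genes from -0.02 to -0.09, the list's median went from 0.05 to -0.09, and HNRNPL, CELF1 and PTBP1 no longer passed. The median also depended on single arrays, at 0.00 without siTARDBP 1, 0.03 without siLuc 1 or siLuc 3 and 0.08 without siTARDBP 2. Of 23 SR proteins and splicing factors, SF1 rose by 0.58 (SE 0.114) and none fell, likewise adjusted over the list alone (adjusted p = 0.797), while the other 2 SF1 probes changed by 0.29 (adjusted p = 0.0511) and -0.03 (adjusted p = 0.9). In the microRNA processing list of 14 genes, TARBP2 (0.35) and TNRC6B (0.35) rose and PRKRA (-0.34) fell, the same counts as adjusted over the list alone (adjusted p = 0.485). A second TARBP2 probe had the opposite sign.

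Lists of growth, protein synthesis and the proteasome also stayed short of the threshold in the camera test. Of 66 cytosolic ribosomal protein genes, RPL22 rose by 0.39 and none fell, likewise adjusted over the list alone (adjusted p = 0.797). MYC (0.45, SE 0.0897) and RRP9 (0.35) rose among 29 ribosome biogenesis genes, with the same counts adjusted over the list alone (adjusted p = 0.325). Of 12 histone genes H4C3 fell by 0.33, and none passed when adjusted over the list alone (adjusted p = 0.469). Proteasome genes went both ways. Of 27 members, PSMD3 (0.85, SE 0.111) and PSMD11 (0.28) rose, and PSMB5, a catalytic subunit (-0.94, SE 0.107), and PSMD2 (-0.34) fell, the same counts as adjusted over the list alone (adjusted p = 0.863).

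Lists of stress and damage responses did not pass either. Of 37 genes of the unfolded protein and integrated stress responses, 3 rose and 2 fell (3 and 2 adjusted over the list alone, adjusted p = 0.469), led by the endoplasmic reticulum chaperone HYOU1 (0.91, SE 0.099). A second HYOU1 probe changed by 0.20 (adjusted p = 0.29). DNAJB4 rose by 0.55 (SE 0.102) among 17 heat shock genes, alone also when adjusted over the list alone (adjusted p = 0.375). Of 41 autophagy and lysosome genes, 4 rose and 4 fell (6 and 6 adjusted over the list alone, adjusted p = 0.797), among them cathepsin D (CTSD, 0.57, SE 0.0919) and ATG4B. In the p53 target list of 27 genes 3 rose and 3 fell (4 and 3 adjusted over the list alone, adjusted p = 0.797), with TP53INP1 at 0.44 and PMAIP1 at -0.42. XIAP, an inhibitor of caspases, rose by 0.39 as the only changed gene among 22 apoptosis regulators, over all genes and adjusted over the list alone (adjusted p = 0.775). DNA repair genes went both ways, with 4 of 34 higher and 6 lower, the same counts as adjusted over the list alone (adjusted p = 0.797), including BRCA1 (-0.48, SE 0.097), FANCE (-0.41) and the mismatch repair gene PMS2 (0.52, SE 0.096). SRXN1 (-0.31) fell among 16 NRF2 targets and HERC5 (-0.28) among 40 interferon response genes, and neither list had a changed gene when adjusted over the list alone (both adjusted p = 0.797).

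Inflammatory and matrix genes were mixed as well. In the NF-kB list of 20 genes 3 rose and 3 fell (4 and 4 adjusted over the list alone, adjusted p = 0.797), with CCL2 (0.46, SE 0.0903) and IL6 (0.40) higher and IL1B (-0.37) lower. Of 42 extracellular matrix and adhesion genes, 3 rose and 8 fell (6 and 8 adjusted over the list alone, adjusted p = 0.797). Collagens were found on both sides, with COL6A1 at 0.52 (SE 0.101) and COL7A1 (-0.58, SE 0.111) and COL6A3 (-0.40, SE 0.0927) lower. Of 20 TGF-beta and YAP targets, TGFB2 rose by 0.54 (SE 0.102), and CCN2 (-0.47, SE 0.0988), TAGLN (-0.41) and TGFBR2 (-0.32) fell, the same counts as adjusted over the list alone (adjusted p = 0.797).

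Markers of cell types were read as levels and changes, without assigning a type to the cells. A tested marker is not necessarily above background. Of those tested, 3 of 12 mesenchymal, 2 of 8 epithelial, 2 of 5 leukocyte and 0 of 5 hepatocyte markers exceeded the background limit on no array. Of 18 mesenchymal markers 12 were bright enough to be tested. Vimentin (VIM) was at 14.29 with siLuc, with a log2 change of 0.00 (adjusted p = 0.988), and of the 12 SNAI2 (0.47, SE 0.0938) and ZEB2 (0.42) rose and ACTA2 (-0.42, SE 0.0951) fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.384). Of 28 hepatocyte markers 5 were bright enough to be tested. Albumin (ALB) was at 7.08 with siLuc and 7.11 with siTARDBP, and ASGR1 (-0.37) and AFP (at least 1.03-fold) fell from levels close to background, the same counts as adjusted over the list alone (adjusted p = 0.375). When each of the 6 arrays was left out in turn, ASGR1 lost its call in 5 cases (-0.24 without siTARDBP 3) and AFP in 4. KRT19 rose by 0.30 among 8 tested epithelial markers, alone also when adjusted over the list alone (adjusted p = 0.48). CD68 (-0.67, SE 0.112) fell among 5 tested leukocyte markers, alone also when adjusted over the list alone (adjusted p = 0.797), but of its other 2 probes 1 rose by 0.52 and 1, at 10.45 with siLuc, stayed short of the threshold (0.00, SE 0.099), so the direction for CD68 is open. Of 22 endothelial markers 4 were tested, too few for a list test, and none passed, over all genes or adjusted over the list alone, with ROBO4 not above the background limit on any siTARDBP array (adjusted p = 0.103) and CD34 at 0.13 (adjusted p = 0.447). None of 12 reference genes passed either way (camera adjusted p = 0.797), and YWHAZ (0.27, adjusted p = 0.105) and TBP (0.21, adjusted p = 0.156) had the smallest p-values.

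In a few lists that did not pass, the signs of median, mean and test differed. The interferon, SR protein, ribosomal protein, NF-kB and NRF2 lists had medians just below 0 (the lowest -0.02) and an upward camera direction relative to the other genes. The leukocyte list had a median of 0.04 with a mean of -0.11 and a downward direction, and the matrix list a median of 0.03 with a mean of -0.01 and an upward direction. These signs depend on single arrays. The median turned to -0.07 for the leukocyte and -0.02 for the matrix list without siLuc 3, and to -0.03 for the leukocyte list without siTARDBP 3. The direction of the matrix list turned downward without siLuc 3 and without siTARDBP 1. The medians of the other 5 lists also rose above 0 without at least 1 array, with 0.05 for NRF2 without siLuc 1 as the highest, and the directions of the ribosomal protein and NRF2 lists turned downward without siLuc 2.

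Of the 107 genes named by rule that passed the threshold, 40 lost the call when at least 1 array was left out, and 26 of the 47 that rose lost it with median scaling. PSMD11 (adjusted p = 0.0822 to 0.142), NDUFB10 (0.0526 to 0.184) and HERC5 (0.0764 to 0.136) lost it whichever of the 6 arrays was left out. ANKRD37, ASGR1, ATP5F1D, DDB2, ELOVL6, GABARAP, H4C3, PDIA4, PTBP1, SRXN1 and TNRC6B lost it in 5 of the 6 cases.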

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

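The test in this part was chosen after the gene results were seen. Probes that the annotation does not tie to a single gene stayed outside the gene comparison, and some of them differed between the groups. Of 5126 such probes that passed the intensity filter, 64 were higher and 32 lower in siTARDBP than in siLuc (limma, Benjamini-Hochberg adjusted p under 0.05 over these probes), and 753 had an unadjusted p under 0.05. Both the called share and this share were smaller than among the 11391 genes, where 1313 passed and 2917 had an unadjusted p under 0.05. The log2 changes of the unnamed probes reached 1.43 and -1.18. They were set apart because data outside the main measurement differed from the controls. No explanation was tested, since these probes have no gene name here.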

How the results depend on the processing

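Median scaling, cyclic loess, the offset of 16, the filter at the background limit, the settings without or with a block for the arrays numbered 2, the lists without PFKP at either correlation, and the TARDBP fits without moderation and against 1.5-fold were chosen after the data were seen. The neqc fits with median scaling and with cyclic loess and the detection p under 0.01 in all 6 arrays were planned and not run, because the table holds neither detection p-values nor control probes. TARDBP, with changes from -1.25 to -0.91, passed the threshold except without moderation of the variances (-0.98, adjusted p = 0.0643), where the spread rests on its own 6 values, and against a minimum of 1.5-fold (-0.98, adjusted p = 0.195). The count of changed genes, 1313, lay between 999 and 1652 except as follows. It was 139 (64 higher, 75 lower) without moderation of the variances, 22 (9 and 13) for changes tested against 1.5-fold, 735 (159 and 576, 701 of them shared with the 1313) with median scaling and 573 (293 and 280, 543 shared) without both arrays numbered 2, where fewer arrays were fitted. Leaving out 1 array gave 748 to 1291 (366 to 578 higher, 382 to 713 lower), with 748 without siTARDBP 3 (722 shared) and 822 without siLuc 2 (774 shared). The cause of the other differences was not tested. The glycolysis list passed in every setting run for lists except with an estimated correlation (median -0.14, adjusted p = 0.369, and without PFKP -0.14, adjusted p = 0.393). Its median ran from -0.19 to -0.12 over single arrays left out, and was -0.11 (adjusted p = 0.044) without both arrays numbered 2. With median scaling, where the median of all genes was -0.09, that of the glycolysis list was -0.27. Lists past the threshold numbered 5, with 3 (without siTARDBP 2) to 6 when 1 array was left out, 3 without both arrays numbered 2, 4 without PFKP, 6 with no filter on dim probes, 6 with median scaling, 7 by fry (pentose phosphate, adjusted p = 0.00858, and ribosome biogenesis, adjusted p = 0.0339, in addition, both upward) and 0 with an estimated correlation, with or without PFKP. Of the 107 named genes past the threshold, 49 kept it in every setting run for all of them, and none reversed. Both groups carry replicate numbers 1 to 3. With the replicate block 1422 genes passed (1293 shared). Deviations from the group means correlated between same-numbered arrays with r = 0.116, 0.131 and 0.027, and siLuc 3 correlated best with siTARDBP 2 (0.038). Same-numbered arrays had similar shares of probes above the background limit (siLuc first, 31.5% and 32.5%, 35.1% and 34.2%, 29.3% and 29.1%). Whether the numbers pair the samples or mark a batch stays open, and the main fit did not use them. The arrays show about 29.1% to 35.1% of probes above background, which limits changes of dim genes, TARDBP included.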

Other observations

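The tests of opposed probes by chance, probe difference, brightness trend and background on all 6 arrays, of the pseudogene probe's rank, of PFKP alone and of the hypoxia-inducible factor targets were chosen after the results were seen, and the others before.

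Some genes had probes that passed the threshold in opposite directions. These were CD68, ITGA3, MYLK, NET1, OPA3, RWDD1, SMARCD1, TFAP2A and TMEM179B. In TFAP2A, a transcription factor, the brightest probe fell by 0.54 (11.52 to 10.98) while the other 2 rose by 0.83 each (from 7.43 and 7.31). RWDD1 showed -0.70 in the bright probe and 0.66 in the dim probe. In 8 of the 9 genes the brighter probe was the lower in siTARDBP, MYLK being the exception. Over all 3094 genes with at least 2 tested probes, 113 (3.7%) had probes that differed in their response in a limma test of the probe difference (Benjamini-Hochberg adjusted p under 0.05). The offset compresses the changes of dim probes, so a bright and a dim probe of 1 gene can differ in size for that reason. The 113 are therefore not a count of genes whose transcripts responded differently. The authors' log2 values gave the same 9 genes, while median scaling kept 6 of them, each with the brighter probe lower.

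For false calls, 9 of 182 genes with at least 2 probes past the threshold, or 4.9% (exact 95% interval 2.3 to 9.2) against the 5% that the threshold allows, decided nothing. A later comparison argues against false calls for the number as a whole, though not for each gene, since unchanged probes with uniform, independent p-values would give 2.17 such genes among 805 other probes of 599 genes (exact Poisson test of at least 9, p = 0.000424). A trend of the normalisation with brightness is left open. Probes as dim and as bright as these differed by -0.011 over all kept probes, against a smallest gap of 0.77 between opposed probes. Quantile normalisation holds such an average near 0, so the comparison could not have shown a trend. Noise of dim probes is argued against in 6 genes, whose opposed probes exceeded the background limit on all 6 arrays, and stays open for ITGA3, MYLK and SMARCD1, because the planned test (0% of genes missed the limit in both groups) passes a probe through the group in which it is brighter. Probes of different transcripts, the biological candidate for a splicing regulator, may be involved but were not separated from other genes by accession (4 of 9 against 71 of 173, odds ratio 1.15, interval 0.22 to 5.54, Fisher's exact p = 1).

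The TARDBP probe fell less than the TARDBPP3 probe. Whether the pseudogene's probe also reads TARDBP messenger RNA stays open, because no probe sequence was compared, and its rank of 1 among 11391 genes is what drew attention to it and tests nothing. After removal of each array's background mode, the decrease was 4.25-fold for TARDBP (2 to 8.24 over pairs of arrays) and 10.85-fold for TARDBPP3 (6.92 to 16.95), a ratio of 2.55. As fitted, before that removal, the decreases were 1.98-fold and 4.69-fold, so the removal did not bring the ratio of the 2 probes closer to 1. Whether compression of the dimmer TARDBP signal by background contributes to the difference is left open, because the ranges overlap. No biological explanation was tested, and the size of the knockdown is less certain than its direction.

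For the glycolysis list, PFKP alone is not the whole source at the preset correlation, where the other members still passed (camera adjusted p = 0.0182, median -0.14), while with an estimated correlation they did not (adjusted p = 0.393). For the list with PFKP, adjusted p ran from 3.82e-05 over the other settings to 0.369 with an estimated correlation. Of random lists matched on brightness, 0.02% had a median as low, so the list fell relative to equally bright genes after normalisation. Quantile normalisation gives every array the same distribution of values. These draws therefore cannot test a general fall of bright genes before normalisation, and they were not run with median scaling. A decline shared with hypoxia-inducible factor targets outside glycolysis may contribute and stays open (median -0.12, adjusted p = 0.124). The knockdown as the biological source is a hypothesis, and the loss of the call with an estimated correlation limits it. The estimated correlation was 0.0166 for glycolysis, near the preset 0.01. It was -0.0045 for the G1/S list, which also lost its call. A correlation above the preset therefore cannot account for the loss in G1/S. With an estimated correlation, camera refers its statistic to a distribution set by the small number of arrays, not by the number of genes. This raises p even at a similar correlation. Unadjusted p went from 0.000146 to 0.0231 for glycolysis and from 0.000472 to 0.0141 for G1/S. The losses therefore cannot tell correlated genes or an absent shift from the small number of arrays, and the share of each was not tested.

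Other divisions of the 6 arrays into 3 and 3 are too few, 10 with the real one, for a share under 0.05. The real division gave 1313 genes against at most 0 in the others, 5 lists against at most 1, and a glycolysis camera p of 0.000146 against 0.0128 at the lowest, and 1 of the 10 divisions, the real one, reached each of these values.

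CDK6, which has been described in other cells as repressed by TDP-43, fell here from 10.62 ± 0.12 to 9.21 ± 0.063 (n = 3 each), with changes between -1.48 and -1.36 when any 1 array was left out. PTBP3 fell by 1.07 and its second probe by 0.92, while PTBP1, its paralogue, rose by 0.31, a call lost with median scaling, and the difference between them was not tested.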
